A study of Gorilla gorilla with 12 samples.

How the data were processed

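The series measured gene expression in cultured fibroblast lines from gorillas, with 1 expression array per culture and 12 arrays in all. Per the labels, 11 arrays held RNA of 11 lines harvested under the same standard conditions, 6 from females and 5 from males, with donor ages from 2 to 35 years. The remaining array held RNA of a second culture of male line 2, harvested at 50% confluence. Lines are named here by the sex in the labels and a running number, which pairs nothing. Each standard array was another animal, so p-values measure the spread between lines of different animals, and the number of arrays limits the precision.

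The deposited values are intensities on a linear scale, 1 whole number per probe set and array, for 12625 probe sets. The summarising software, the scaling and the floor are not given in the sources used here. In the deposited values themselves, the lowest intensity was 100 on all 12 arrays and the highest was 43135, and between 40.1% and 49.2% of the probe sets of an array stood exactly at 100. The trimmed mean intensity lay between 411.4 and 427 on all 12 arrays. Median intensities of the arrays labelled female 1 to 6 were 140, 126, 127, 118, 126 and 139. Those of males 1 to 5 were 124, 148, 106, 142 and 133, and the array at 50% confluence had a median of 105. A value at the floor is only an upper limit, so a difference against it is given as at least a fold, or as both intensities where normalization raised the fold above that of the deposited values.

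Probe sets of this array type were designed on human sequence and were hybridised with gorilla RNA, so a base difference under a probe lowers its intensity whatever the level of the transcript. No level of one gene is read against that of another. Levels of probe sets do enter the 3' to 5' ratios, the filter on mean level, the choice of probe sets and the matching of random lists. The probe annotation gave 1 gene symbol for 10961 probe sets and several for 545, and it did not list 1119. Only probe sets with 1 symbol are named. Of 8229 distinct symbols, 7742 were found in the gorilla gene table of assembly NHGRI_mGorGor1-v2.1, which was used for names only. No genome came with the data, and no coordinates are given. The 67 control probe sets served as a check of RNA quality and were left out of all tests.

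Intensities were taken to log2. The planned floor of 16 changed nothing because of the deposited floor of 100. Median log2 values of the arrays ran from 6.71 to 7.21, a difference above the limit of 0.1 set beforehand, so arrays were quantile normalized. A probe set was tested if its mean log2 value exceeded the 40th percentile of all means, which left 7541 probe sets and 5486 genes. These choices, the tests, the lists and the rule for named genes were fixed before the data were examined.

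Male minus female differences and slopes per 10 years of donor age, with sex as a covariate, were fitted over the 11 standard arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The second culture of male line 2 was compared with the standard culture of that line without a p-value, since each condition had 1 array. Folds between both cultures are from quantile-normalized values, while intensities are printed as deposited, so their ratio differs somewhat from the fold. Probe sets differing by 2-fold or more were counted, and each was set against the range of the 11 standard arrays. Of 40 gene lists with 994 genes, 800 genes had a probe set, and 38 lists had at least 5 tested genes. Each gene was represented by the tested probe set with the highest mean. Lists were tested for sex and age with camera at a preset correlation of 0.01. An estimated correlation and fry, which tests whether the genes of a list move on balance one way, were alternatives. For confluence and for the variation between lines, a list's median was placed among 10000 random lists of the same size, matched in 10 bins of mean level. The difference of a single value between the sexes was tested two-sided over all splits of the 11 arrays into 6 and 5 by an exact permutation test.

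Named genes followed a rule. For sex they were the probe sets past the threshold, every Y-linked gene that passed the filter, and XIST. For age they were the 5 with the smallest p per direction, since none passed. For confluence they were the 12 largest differences per direction outside the range of the standard arrays with the brighter value above that array's median, and 4 members of each list outside the middle of the random lists. For variation they were the 15 genes with the largest SDs among probe sets with a mean above the median, and up to 4 members of each list above the random lists. Other genes named were chosen after their values were seen.

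The steps were tested on simulated arrays made from the real means and spreads of the probe sets. With 200 probe sets changed between the sexes, 37.5% were recovered at a 2-fold change and 78% at a 4-fold change, over 7538 and 7540 tested probe sets. With 200 probe sets given a 2-fold slope per 10 years of age, 90.5% were recovered over 7537 probe sets. Smaller slopes, as most of those reported below are, were not simulated, so this share does not hold for them. A shift of 0.5 log2 units in 1 list was called for sex and for age with no other list called, in noise without correlation between genes. In the simulated pair of cultures such a list stood above all random lists, and 2 other lists of 38 stood outside their random range.

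Alternatives covered the normalization, the floor, the filter, covariates, the variance model, array weights, adult donors only, each line left out in turn and the choice of reference for the 50% culture. A fit with both cultures of male line 2 and line as a random block could not be made, because limma estimates no correlation from 1 repeated line. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.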

Results

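Expression was measured in fibroblast lines, cultured connective tissue cells, of 11 gorillas harvested under standard conditions. The lines labelled female came from donors of 19, 19, 35, 26, 30 and 2 years. Those labelled male came from donors of 19, 26, 24, 18 and 3 years. A second culture of male line 2, from the 26-year-old donor, was harvested at 50% confluence, when the cells covered only part of the dish. Between 50.8% and 59.9% of the 12625 probe sets stood above the floor of the deposited intensities on an array. The ratio of 3' to 5' intensity, a measure of intact RNA, ran from 0.821 to 1.34 for GAPDH and from 0.672 to 1.19 for ACTB. It followed donor age in part, downward for GAPDH and upward for ACTB.

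Sex-linked genes were read first, as a check of the labels. RPS4Y1, a Y-linked gene for a ribosomal protein, had intensities of 2662 to 4363 in the 5 male lines, with a mean of 3647 ± 748 (SD, n = 5). It had 100, 100, 100, 100 and 115 in 5 of the lines labelled female, so it was at least 35.3-fold higher in the male lines than in those. In the line labelled female 3, from the 35-year-old donor, its intensity was 2595, or 71.2% of the male mean. The culture of male line 2 at 50% confluence had 3540. DDX3Y, an RNA helicase gene of the Y chromosome, had 175 in the line labelled female 3 and was at the floor in the other 5 female lines, while the male lines had 100 to 230. KDM5D, a Y-linked histone demethylase gene, had 149 in that line, 100 to 102 in the other female lines and 100 to 176 in the male lines. PRKY reached 154 in the line labelled female 6 and 290 in male 5. AMELY and TMSB4Y did not separate the sexes, at log2 differences of -0.28 and -0.42, male minus female. Other Y-linked genes were too dim for the filter. SRY, ZFY, NLGN4Y and TXLNGY were at the floor on all 12 arrays, those of males included. EIF1AY, USP9Y and UTY had at most 123, 129 and 120 on any array. XIST, the RNA that coats the inactive X chromosome, was at the floor on every array but female 5, where it had 131, so this probe set was not informative on sex (log2 difference -0.068, exact permutation p = 1).

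The mean of 15 genes of the X inactivation and escape list, many of which are known in humans to be transcribed from both X chromosomes, was 9.28 in log2 units in the line labelled female 3. The male lines had 9.40 ± 0.13 (SD, n = 5), and the other female lines had 9.76 ± 0.05 (SD, n = 5). By label, RPS4Y1 was 4.36 log2 units higher in males (exact permutation test, two-sided, p = 0.00433). The mean of 6 Y-linked probe sets was higher by 0.82 (exact permutation test, p = 0.0173, adjusted p = 0.452 over the lists), with a median of 0.34 and 2 of the 6 negative, so RPS4Y1 made up most of that mean. No line was moved between groups, and every male minus female direction given here includes the line labelled female 3 among the females.

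**Figure D1:**
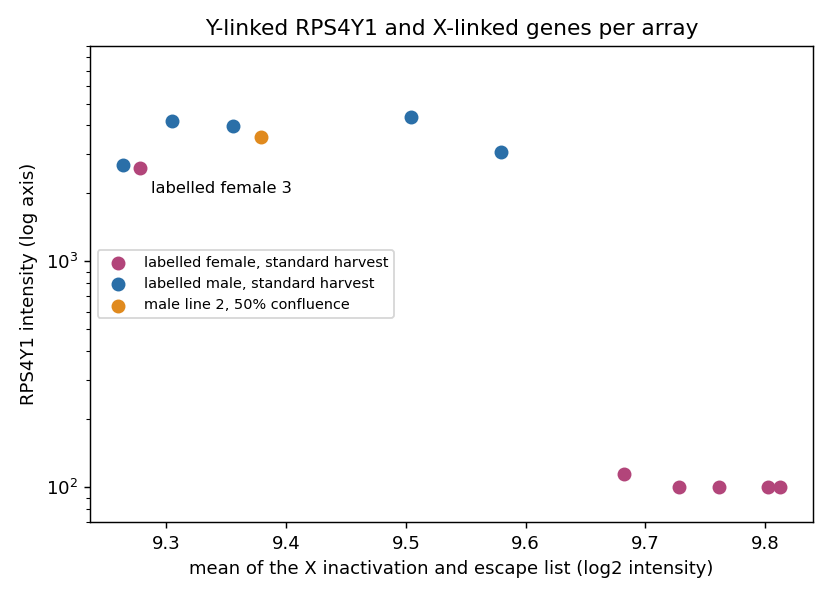
RPS4Y1 intensity (log axis) against the mean log2 intensity of the X inactivation and escape list, 1 point per array, coloured by the sex in the labels. The line labelled female 3, at 2595 and 9.28, sits beside the male arrays, and the other 5 female lines have 100 to 115 and 9.68 to 9.81.

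Genes of DNA replication and mitosis stood higher in the lines labelled male. In the cell cycle S list, genes of DNA synthesis, 35 of 36 members had a positive male minus female difference, with a median of 0.73 log2 units. Examples were the replication licensing genes MCM4 (1.17, SE 0.34) and MCM3 (1.21, SE 0.41), CDC45 (1.33, SE 0.45), a part of the replicative helicase, and RRM2 (1.18, SE 0.39), a subunit of ribonucleotide reductase. CDC45 was at the floor in females 1, 3, 4 and 6, and RRM2 in females 1, 3 and 4 and in male 2. Their differences rest in part on such values. In the cell cycle G2M list, genes of mitosis, all 38 members were positive, with a median of 0.55. The X inactivation and escape list was lower in the lines labelled male, with 14 of 15 members negative and a median of -0.23. Its 4 members with an unadjusted p under 0.05 were DDX3X (-0.58), ZRSR2 (-0.51), CDK16 (-0.44) and MAOA (-0.78).

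With camera's preset correlation these were 3 of 38 lists called, at adjusted p = 1.1e-18 for S phase, 4.48e-14 for G2M and 0.0062 for the X list. Each call was lost with an estimated correlation, where the adjusted p of each was 0.577, and fry called 0 lists. The mean of the S list per line, 8.65 ± 0.67 (SD, n = 5) in males and 7.94 ± 0.43 (SD, n = 6) in females, differed by 0.71 (exact permutation test, p = 0.0649, adjusted p = 0.494 over the lists). That of the G2M list differed by 0.61 (exact permutation test, p = 0.121), and that of the X list by -0.28 (exact permutation test, p = 0.039, adjusted p = 0.452). No member was called over all probe sets. Adjusted over the list alone, 8 members of the S list passed, MCM4, MCM3, CDC45, RRM2, GINS1, TYMS, E2F1 and FEN1, and 0 of the G2M and X lists did. With each line left out in turn, the S difference ran from 0.48 (without male 3) to 0.91 (without male 2). The G2M difference ran from 0.44 without the line labelled female 3 to 0.81 without female 5. That line labelled female 3 had the lowest S and G2M means of the standard lines (7.56 and 7.59). Camera at the preset correlation called both cell cycle lists in all 11 runs. The X list call was also lost without female 1 (adjusted p = 0.0516), female 2 (0.080), male 2 (0.0689) or male 5 (0.0709), with no filter on dim probe sets (mean -0.16, adjusted p = 0.109) and in adult donors only (0.067). Its mean difference was -0.22, -0.22, -0.21 and -0.25 without these lines and -0.28 in adults, against -0.28 in the fit reported. Without the line labelled female 3 it was -0.36, the largest of these runs, and the X and Y-linked lists were both called. Ribosomal protein genes were mostly higher in the lines labelled male, with 29 of 37 positive, at a camera adjusted p of 0.0652 that missed the threshold.

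limma called 0 of 7541 probe sets between the sexes. At an unadjusted p under 0.05 there were 397, against 377 by chance, 202 higher and 195 lower in males. RPS4Y1 came nearest (log2 4.36, SE 0.69, adjusted p = 0.0968), with LAT, an adaptor of T cell receptor signalling, at the same adjusted p (-1.52, SE 0.25). Without the line labelled female 3, RPS4Y1 was the 1 probe set called, at log2 5.14 and an adjusted p of 1.19e-09. With the 50% confluence array in place of the standard array of male 2, or with median scaling of the arrays, limma called 2 probe sets, RPS4Y1 and one that carries several gene symbols.

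**Figure D2:**
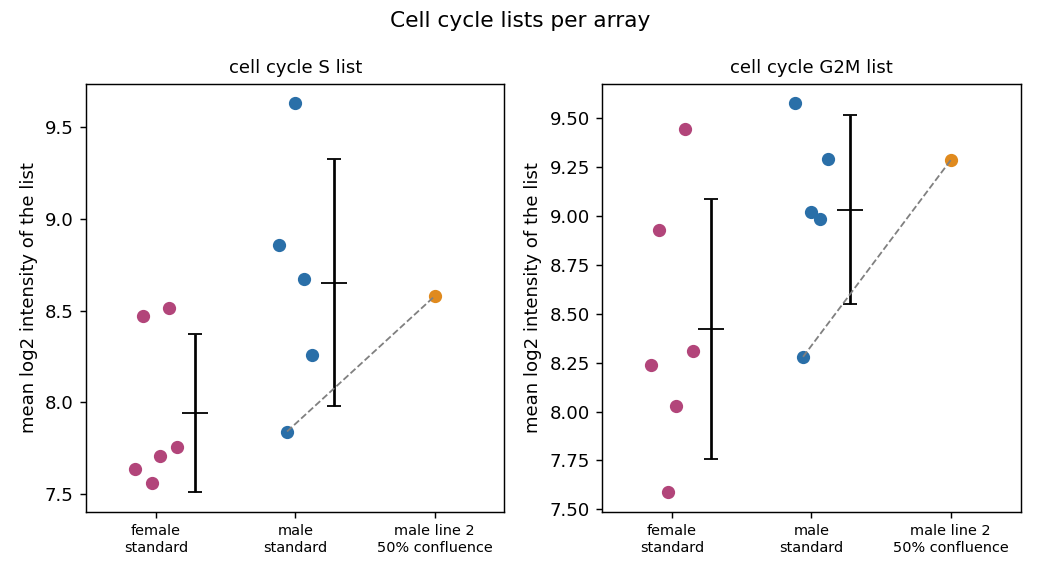
Mean log2 intensity of the cell cycle S list (left) and G2M list (right), 1 point per array, by group, with the mean and SD of the standard arrays as bars. The dashed line joins both cultures of male line 2, whose S list mean was 7.84 at the standard harvest and 8.58 at 50% confluence.

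Donor age, as given in the labels, was set against expression over the same 11 lines, which include 2 donors under 10 years and 9 adults. The array labelled female 3, the oldest donor, may hold another animal's cells, which would make its age wrong too. A wrong sex label would make its sex covariate wrong. Genes of the contractile apparatus had mostly negative slopes with age. Smooth muscle actin ACTA2 had a slope of -1.004 log2 units per 10 years (SE 0.31), calponin CNN1 -0.78 (SE 0.24) and vinculin VCL -0.47 (SE 0.13), and 16 of 18 members of the contractile smooth muscle list were negative. All 8 skeletal muscle markers were negative too, led by the cardiac actin ACTC1 (-1.34, SE 0.45). Cytokine genes leaned the other way, 12 of 17 positive, led by the inflammatory cytokine IL6 at 1.54 (SE 0.30), and so did the metallothioneins, metal-binding proteins, with 6 of 6 positive. The 3' to 5' ratios, the measures of RNA quality, moved with age beside these groups but in opposite directions. They therefore show no common rise or fall of RNA quality with age. The 3' to 5' ratio of ACTB was 0.840 and 0.672 in the donors of 2 and 3 years, 0.865 to 1.083 in those of 18 to 26 years, and 1.175 and 1.188 in those of 30 and 35 years. That of GAPDH was 1.285 and 1.304 in the youngest and 0.821 and 0.869 in the oldest, with 0.963 to 1.343 between.

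With camera's preset correlation 6 of 38 lists were called, namely contractile smooth muscle (adjusted p = 2.2e-07), metallothioneins (0.00123), cytokines and chemokines (0.00432), skeletal muscle markers (0.00786), cell cycle G2M (0.0205, negative) and cholesterol biosynthesis (0.0383, negative, 17 of 21 members). No call held with an estimated correlation, where the smallest adjusted p was 0.394, and fry called 0. Adjusted over the list alone, 3 contractile members (VCL, CNN1 and ACTA2), 2 skeletal muscle markers (ACTA1 and ACTC1) and IL6 passed, and none of the metallothionein, G2M or cholesterol lists. Of the 12 basement membrane genes the collagen IV genes COL4A1 and COL4A2 passed in this way, at slopes of -1.09 and -0.76, although the list itself was not called (adjusted p = 0.0956). So did H2BC12 (0.47), IGF1 (-0.42) and FST (0.46), 1 gene each of the core histone, IGF axis and TGF-beta lists, which were not called either. H2BC12 had 962 in the line labelled female 3 and 179 to 432 in the other standard lines. Among the 9 adults alone the mean slope of the contractile list was -0.03 (camera adjusted p = 0.959) and that of the metallothioneins 0.14 (adjusted p = 0.455). In adults without the line labelled female 3 they were 0.13 and -0.29, the other sign, and camera called 0 lists. Without the line labelled female 3, the mean slope of the cytokine list was 0.11 (adjusted p = 0.778) and that of the G2M list 0.010 (adjusted p = 0.872). The cytokine call was also lost with log2 of age (adjusted p = 0.115), donors under 10 years against adults (0.394), the filter at the 60th percentile (0.0994, with a mean slope of 0.30 against 0.29) and the floor of 200 (0.0874, with 0.20). The skeletal muscle call was lost without female 6 (adjusted p = 0.200), in adults only (0.422), with no filter (0.145), the filter at the 60th percentile (0.0994) and the floor of 200 (0.0666). Its mean slope, -0.31, was -0.33, -0.31, -0.12, -0.31 and -0.24 in these, so among these it was smaller with no filter and the floor of 200 alone. In adults without the line labelled female 3 it was -0.088 (camera adjusted p = 0.711). The G2M call was lost also without male 2, female 4 or male 5 (adjusted p = 0.0687 to 0.5003), with log2 of age (0.312), donors under 10 years against adults (0.713), array weights (0.186) and the floor of 200 (0.369). Its mean slope, -0.125, was -0.054, -0.107 and -0.106 without these lines, -0.083 with the floor of 200 and -0.29 without female 6. The cholesterol slope was 0.090 in adults only (adjusted p = 0.535), the other sign, and its call was lost without any 1 of males 1, 2, 3 and 5 and females 5 and 6 (adjusted p = 0.0529 to 0.662), as well as on values as deposited (0.0616), with median scaling (0.0798), no filter (0.0537), the filter at the 60th percentile (0.0687) and array weights (0.111). The mean slope of this list, -0.086, was -0.017 without male 5 and -0.074 to -0.099 without the other lines named.

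limma called 0 of 7541 probe sets for age. At an unadjusted p under 0.05 there were 410, against 377 by chance, 190 positive and 220 negative. The 10 genes with the smallest p did not pass the threshold. On the positive side were CDA, an enzyme of pyrimidine salvage (slope 0.58, SE 0.10, adjusted p = 0.295), IL6 (adjusted p = 0.401), UBE2H, the activin antagonist FST, and UCN, with slopes of 0.46 to 0.61 and adjusted p = 0.826 for the last 3. The slope of FST was 0.29 without female 6, the donor of 2 years. On the negative side were the keratin gene KRT7 (-0.95, SE 0.17, adjusted p = 0.295), COL4A1, the growth factor gene IGF1 (-0.42), the neurotrophin gene BDNF (-0.41) and skeletal actin ACTA1 (-0.45), the last 4 at adjusted p = 0.826. KRT7 had intensities of 1217 and 953 in the donors of 2 and 3 years and 100 to 662 in the adults. A second KRT7 probe set had a slope of -0.18, and a second one of BDNF -0.31. IL6 had 309 and 125 in the young donors and 14499 in the line labelled female 3, whose age of 35 is uncertain. The other adults had 211 to 2983, and the slope of IL6 was 1.21 without that line. IGF1 and ACTA1 were at the floor on 8 of 11 arrays. The slope of age did not differ detectably between the sexes in any probe set (limma interaction, 0 called, 282 at an unadjusted p under 0.05).

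**Figure D3:**
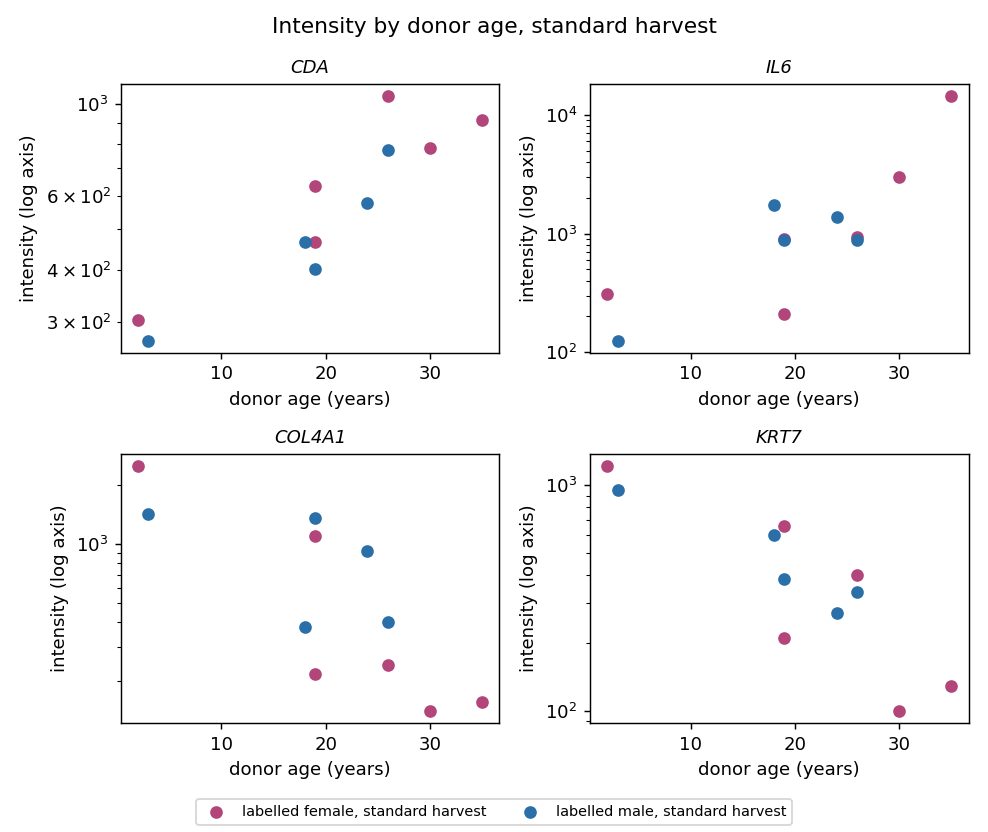
Intensity (log axis) of CDA, IL6, COL4A1 and KRT7 against donor age in years, 1 point per standard array, coloured by the sex in the labels. IL6 runs from 125 in the 3-year-old to 14499 in the line labelled female 3, whose labelled age of 35 is uncertain. KRT7 runs from 1217 in the 2-year-old to 100 in the 30-year-old, and neither gene passed the threshold.

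The labels pair the culture of male line 2 at 50% confluence with its standard culture, 1 array each, so these differences have no replicate check and no p-value. Folds are from quantile-normalized values and intensities are as deposited. The density of the standard harvest is not given in the sources used here. Cell cycle genes were higher in the culture at 50% confluence. In the G2M list 36 of 38 genes were higher, 20 of them by 2-fold or more, with a median of 1.11 log2 units. The checkpoint kinase gene BUB1B had the floor of 100 in the standard culture and 646 in the other, at least 6.46-fold, and cyclin B2, CCNB2, 182 and 848. In the S list 31 of 36 genes were higher, with a median of 0.89, among them RRM1 (3.98-fold) and the DNA ligase gene LIG1, with intensities of 100, the floor, and 323. BIRC5 was an exception among the probe sets, at -1.67 on one and 1.497 on another. Metallothionein genes were higher by a median of 0.94, including MT1H (2.14-fold) and MT1E (1.94-fold), on probe sets that match several members of the family. Cholesterol synthesis genes had a median of 0.42, with the sterol sensor INSIG1 at 2.48-fold, DHCR7 at 2.12-fold, and SQLE and NSDHL at 1.90-fold and 1.88-fold.

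Genes of growth arrest, contraction, matrix turnover and antigen presentation were lower in the culture at 50% confluence. The quiescence and growth arrest list had a median of -0.49, with IGFBP2 at 6346 in the standard and 550 in the other culture, the growth arrest gene GAS1 at 1569 and 487, and the cyclin-dependent kinase inhibitor CDKN1C at 405 and 111. A pair of other CDKN1C probe sets stood at the floor in both cultures and gave no information. In the IGF axis list (median -0.41) IGFBP7 was 4.34-fold lower and STC1 4.10-fold lower. The contractile list had a median of -0.44, or 0.031 with median scaling, with myosin light chain kinase, MYLK, at least 4.91-fold lower and the small heat shock protein CRYAB 3.50-fold lower. Of the matrix proteases and their inhibitors (median -0.32, or 0.17 with median scaling), cathepsin K, CTSK, was 6.52-fold lower, MMP14 3.98-fold and TIMP2 2.74-fold. Other probe sets gave log2 differences of -1.98 and -1.81 for CTSK, -1.88 for MMP14 and -1.87 for TIMP2. The MHC class I and II list had a median of -0.54, with HLA-E 2.51-fold lower, HLA-F 2.29-fold, HLA-G 2.05-fold and HLA-DRA at least 2.08-fold. The HLA-F and HLA-G probe sets match several members of the family, so the gene measured is uncertain. Second probe sets of HLA-F and HLA-G gave log2 differences of -0.93 and -0.64. Beside these lists, the arrays of the pair also differed in signal. The standard array had the fewest probe sets at the floor of the 12 arrays (40.1%) and the highest maximum (43135), and that at 50% confluence the most (49.2%) and the lowest maximum (18027). Their 3' to 5' ratios were 1.301 and 0.990 for GAPDH and 0.865 and 0.857 for ACTB.

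These 9 of 38 lists lay outside the middle 95% of 10000 random lists matched on mean level, where chance would place 1.9 if the genes of a list varied independently. Genes of a list vary together, which this number leaves out. With the mean of the 5 male standard arrays as the reference, the S list had a median of 0.02, inside the random range, and the standard culture of male line 2 had the lowest S list mean of the male lines (7.84). The contractile, MHC and cholesterol medians, at -0.10, -0.20 and 0.21, were inside it as well. The protease median was also inside on values as deposited (-0.32), with median scaling (0.17) and with no filter (-0.035), the cholesterol median (0.29) with no filter, the floor of 200 or the mean over a gene's probe sets, and the contractile median (-0.22) with that mean. Median scaling moved the median difference of all probe sets by 0.44, and with it the contractile median still lay below its random range, at percentile 0.35.

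**Figure D4:**
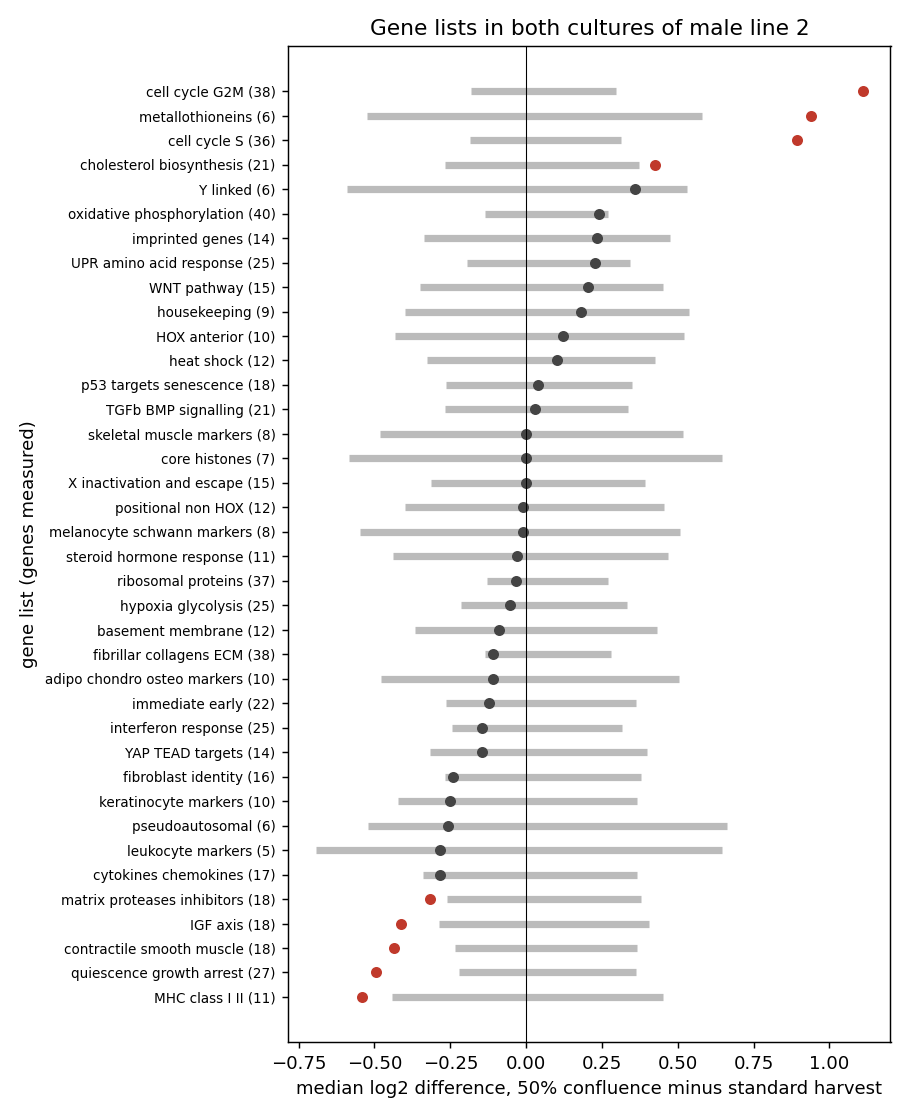
Median log2 difference, 50% confluence minus standard harvest of male line 2, for 38 gene lists (points), with the middle 95% of random lists of the same size and mean level (grey bars). The 9 lists outside their bars are in red, from cell cycle G2M at 1.11 to MHC class I and II at -0.54, and directions are those after quantile normalization, with median scaling turning the contractile (0.031) and protease (0.17) lists. Under that scaling the contractile list still lay below its random lists.

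Of 7541 probe sets, 531 were higher and 545 lower at 50% confluence by 2-fold or more, 134 and 212 of them with a culture at the floor. Among these, 124 and 113 lay outside the range of all 11 standard arrays. Over all probe sets 11.6% lay outside that range. A chance share of 16.7% for 1 more array assumes no ties, and ties at the floor lower it. The array is also a second culture of a line already in the range, so 11.6% cannot be read against 16.7%. Without quantile normalization the counts were 377 higher and 849 lower, and with median scaling 1309 and 231, so the balance of directions depended on the scaling. The largest difference upward outside the range, after BUB1B, was in TGFBI, a secreted matrix protein induced by TGF-beta, at 6.36-fold. It was followed by the protocadherin PCDH9 (5.69-fold), the repair enzyme PCMT1 (5.44-fold), ADGRL2 (intensities of 113 and 443), AP1G2 (4.35-fold), the potassium channel KCNN4 (intensities of 100, the floor, and 422), MICAL2 (4.25-fold), UAP1 (4.15-fold), GP9 (106 and 401), CYB561D2 (100, the floor, and 397) and topoisomerase TOP2A (3.66-fold). ADGRL2 and GP9 were close to the floor in the standard culture, and with a floor of 200 their log2 differences were 1.19 and 1.06, in place of 2.15 and 2.05. Lower were the ribosomal protein RPLP1 (10.2-fold on this probe set), the transcription factor NFATC4 (6.47-fold), the chaperone CALR (5.45-fold), the small GTPases RHOB (5.04-fold) and RHOQ (3.67-fold), INHBC (at least 4.89-fold), thrombospondin THBS1 (4.65-fold), the caveolar protein CAVIN1 (4.38-fold), LRRC32 (3.88-fold), the peptidase MME (3.80-fold), S100A4 (3.58-fold) and FGFR4 (at least 3.47-fold). Other probe sets of the same gene gave smaller log2 differences or the other sign. They were 0.14 for PCDH9, 0.77 and 0.19 for PCMT1, 0.85 for ADGRL2, 0.46 for AP1G2, -0.27 for MICAL2, and 0.89 and 1.74 for TOP2A. Among the lower genes they were -0.60 for RPLP1, -0.86 to -1.51 for NFATC4, -1.40 for CALR, -0.23 for RHOQ, -0.88 and -1.06 for THBS1, -0.41 for CAVIN1 and -0.44 for S100A4. The folds printed for these genes are those of the probe set with the largest difference.

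Both cultures of male line 2 were no more alike than cultures of different animals. Over 7541 probe sets their log2 values correlated at r = 0.914 across probe sets, which are not independent replicates, and 35 of the 55 pairs of different standard lines correlated better (median 0.921, range 0.884 to 0.940). The array at 50% confluence was closest to the line labelled female 5 (r = 0.942), and its own line came 10th of 11. The pair differed by 2-fold or more at 1076 probe sets, against a median of 930 over the 55 pairs.

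Among the gene lists, variation between the 11 standard lines was largest for cell cycle and cytokine genes. Each line had 1 standard culture and 1 array, so this spread holds differences between cultures and arrays as well as between animals. The log2 differences between both cultures of male line 2, harvested differently, had an SD of 0.70, against a median of 0.67 over the 55 pairs of lines. The SD of a probe set's log2 values had a median of 0.41, and 117 probe sets, or 1.6%, had an SD above 1. After RPS4Y1 (SD 2.65), the stromelysin MMP3 had an SD of 2.41, from 100 in 2 lines to 15064 in the line labelled female 3. The collagen gene COL11A1 ran from 100 to 6743, ACTC1 from 181 to 18139, IL6 from 125 to 14499, and the insulin-like growth factor binding protein genes IGFBP2 and IGFBP5 had SDs of 1.91 and 1.82. Other IGFBP5 probe sets had SDs of 0.34 to 1.77. The cartilage proteoglycan ACAN, MFAP4, the Wnt antagonist SFRP1, CCN5, the neuropeptide GAL, CD14, SEMA5A and G0S2 completed the 15 genes, with SDs of 1.52 to 1.84. By list, 14 of 38 medians lay above the middle 95% of matched random lists. They were led by cell cycle G2M (median SD 0.83), cytokines and chemokines (0.82), cell cycle S (0.78), the WNT pathway (0.68), core histones (0.65), contractile smooth muscle (0.61) and quiescence and growth arrest (0.61), with skeletal muscle markers at 0.55. Y-linked genes (0.52), fibrillar collagens and matrix (0.52), YAP and TEAD targets (0.51), TGF-beta and BMP signalling (0.51), imprinted genes (0.50) and matrix proteases (0.49) followed. Ribosomal proteins (0.20) and oxidative phosphorylation (0.29) lay below. Genes of a list vary together, which the random lists leave out, so these places are a description and not a test.

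In the contractile list ACTA2 ran from 885 in male 3 to 17653 in male 5 (SD 1.51) and CNN1 from 100 to 1156. In the matrix list biglycan, BGN, ran from 2408 in the line labelled female 3 to 33087 in male 1. In the TGF-beta and BMP list INHBB had an SD of 1.32 and ID1, a BMP target, 0.84, and in the imprinted list NDN had 0.92 and CDKN1C 0.78. Cell cycle examples were UBE2C (209 to 3896) and PTTG1 (308 to 2556). Without the line labelled female 3, the SD of H2BC12, the median of the core histone list, fell from 0.65 to 0.42. That of H1-2 fell from 0.89 to 0.29, CCL2 from 1.24 to 0.79, TNFAIP6 from 1.16 to 0.76 and TGFBR2 from 0.75 to 0.37. Much of the spread of these genes thus came from that array.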

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

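All tests of explanations in this part were chosen after the result was seen, except the correlation test on growth state in males and females, and the counts of gene lists over other splits of the lines. Among the lines of each labelled sex, a value was set apart where its gap to the nearest line exceeded Dixon's 95% limit for the size of the group. Chance does this for about 1 in 20 groups, or 17 of 334, and 33 were found, 12 of them in the line labelled female 3. Many genes screened had been named for extreme values, so 33 against 17 is no measure of an excess.

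The line labelled female 3 carried RPS4Y1 at 2595 against at most 115 in the other female lines (gap 0.978 of the group's range), with DDX3Y (175, gap 1) and KDM5D (149, gap 0.862) also above the others. Its Y-linked mean (0.62 against the mean of all standard arrays, gap 0.741) and X inactivation and escape mean (-0.27, gap 0.757) stood apart as well, and the X list mean of 9.28 fell inside the male range of 9.26 to 9.58 and outside the 9.68 to 9.81 of the other female lines, as a wrong sex label or another animal's cells on this array would need. A swap with a male array of the series would need a male array without RPS4Y1, and the lowest male intensity was 2662. Male cells mixed into a female culture would need RPS4Y1 below the male range and an X list mean between the means of the sexes. RPS4Y1, at 71.2% of the male mean, was below the lowest male line. The X list mean of 9.28 was not between, as it lay below the male mean of 9.40. A small share of female cells stays open, since these values cannot tell it from none. A wrong sex label may explain the pattern, and no biological explanation was tested.

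In the same line, the core histone list (1.01 above the mean of the standard arrays, gap 0.660) stood above the other lines labelled female. Its member H1-2 (785, nearest 135, gap 0.819), a gene of a linker rather than a core histone, led it. Cytokine genes (1.24, gap 0.704), with CXCL8 (565, nearest 100, gap 1), stood above those lines as well. TGFBR2 had 5600 (nearest 1566, gap 0.678). The pseudoautosomal list mean was lowest there (-0.15, gap 0.683), and so was ACTC1 (181, nearest 2618, gap 0.631).

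Both cultures of male line 2 were no more alike than different lines. With the cell cycle mean regressed out of every probe set, 26 of the 55 pairs were still more alike than this pair, in place of 35. The regression covers the cell cycle alone, so the share of growth state stays open. Lower quality of the standard array stays open: its mean r of 0.913 with the other standard arrays lay inside their range of 0.906 to 0.927 and excludes nothing, and of the 12 arrays it had the fewest probe sets at the floor (40.1%) and the highest maximum (43135). Whether the array at 50% confluence holds another line cannot be told apart from an effect of the harvest condition with 1 array: its deviations from the mean of the standard lines ranked male line 2 7th of 11 at r = -0.09, and 4th at r = 0.038 after the regression, and male 1 was best each time. Its RPS4Y1 intensity of 3540 shows male cells and does not tell males apart.

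The cell cycle lists were higher in lines labelled male. Their members vary together between lines, and the exact permutation p for the mean of both lists was 0.0736, so a grouping of 5 lines by chance may give such a difference. Growth state at harvest could act as well, since the same mean differed by 0.88 between the cultures of male line 2 and by 0.66 between the sexes. Over 5406 other genes, which are not independent replicates, the difference between those cultures correlated with the male minus female difference without male line 2 at r = 0.217, and 9.52% of the splits of the other lines gave as much, so this stays open. A difference by sex stays open and untested beyond this.

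Of 100 splits of the 11 lines, the real one included, 66 gave at least the 3 lists called by sex, and the highest other gave 10. For age, 27 of 100 assignments of the ages gave at least the 6 lists called, and the highest other gave 10, so chance is not excluded for either. For single probe sets the real counts were 0 for sex and 0 for age by limma (397 and 410 at an unadjusted p under 0.05), which all 100 splits and all 100 assignments reach by necessity, so these counts tested nothing. The highest other counts were 13 and 1.

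IL6, IGF1, ACTA1 and FST were screened because their p for age was among the smallest, so a gap of the youngest donors in them is no separate finding. In male 5, aged 3, IL6 was lowest (125, nearest 880, gap 0.740), and IGF1 (215, nearest 100, gap 1) and ACTA1 (188, nearest 100, gap 1) were highest. In female 6, aged 2, FST was lowest (2716, nearest 6303, gap 0.703), ACTA1 was highest (343, nearest 135, gap 0.682), MMP1 was at the floor of 100 (nearest 335, gap 0.6254), and PRKY was highest (154, nearest 102, gap 0.823).

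Within their sex, female 5 had the lowest IGF axis mean (-0.45, gap 0.686) and IGFBP7 (693, nearest 2682, gap 0.667) and the highest XIST (131, nearest 100, gap 1). Female 1 was highest in THBS1 (2121, gap 0.636), MYOG (550, gap 0.634) and GREM1 (3265, gap 0.629), and female 2 lowest in S100A4 (624, gap 0.628) and IRS2 (100, gap 0.637). Male 1 had the highest trimmed mean intensity (421.1, gap 0.733) and the lowest imprinted gene mean (-0.27, gap 0.719). Male 3 was highest in the heat shock mean (0.20, gap 0.734) and GP9 (118, gap 0.983), male 4 in H1-2 (196, gap 0.802), and male 2 was lowest in RPA3 (126, gap 0.787).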

How the results depend on the processing

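The floor of 200, the restriction to probe sets above the deposited floor, the cell cycle covariate and the fit to adults without the line labelled female 3 were chosen after seeing the data. The planned floor of 64 lay below the deposited floor of 100 and was not run, nor was the block of both cultures of male line 2. limma called 0 probe sets for age under every alternative run (410 at an unadjusted p under 0.05 in the fit reported). For sex, 2 were called with median scaling and 2 with the 50% confluence array in place of the standard one. Lists called by sex, 3, were 5 with the filter at the 60th percentile, 8 with donor age as a covariate, 6 with the 50% confluence array, 5 with trend and robust eBayes, 1 with the cell cycle covariate, 0 with an estimated correlation and 0 with fry. Lists called by age, 6, were 3 with the stricter filter, 3 with the floor of 200, 0 in adults without the line labelled female 3, 0 with an estimated correlation and 0 with fry. Probe sets differing 2-fold between both cultures, 1076, were 536 with the floor of 200, 561 above the deposited floor on all 12 arrays, 273 against the mean of the male arrays, 2830 at 1.5-fold and 237 at 3-fold. Lists above the random range in variation, 14, were 9 in male lines only, where fewer arrays entered. With each line left out in turn, probe sets called by sex ranged from 0 to 1, those by age from 0 to 0, lists by sex from 2 to 5, lists by age from 5 to 8, lists in variation from 12 to 16, and the RPS4Y1 difference from 4.20 to 5.14. Signs turned for the protease (0.17) and contractile (0.031) medians by confluence with median scaling, which moved the median difference of all probe sets by 0.44. The contractile median still lay below its random range there, at percentile 0.35. Signs also turned for the G2M list by sex with the cell cycle covariate (-0.078), which by construction removes it. By age they turned for cholesterol in adults only (0.090), for G2M without the line labelled female 3 (0.010), and, in adults without that line, for the contractile (0.13), metallothionein (-0.29) and cholesterol (0.071) lists. Beyond fewer lines, probe sets or thresholds, the cause was not tested. Signal near the floor is a limit, with 36.5% of probe sets above it on all 12 arrays.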

Other observations

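The values below were picked after they were seen, and none was tested. Some genes set single lines apart from the other standard lines. Male 3 and male 4 carried MFAP4, a microfibril protein, at 6674 and 4295, against at most 869 in every other standard line, and GAL, a neuropeptide gene, at 1255 and 1308, against at most 796. They shared low COL11A1, at 100 and 131, with female 5 at 121, while male 2 had 6743. CD14, a receptor of bacterial lipopolysaccharide, had 1576 and 1092 in these 2 lines and 1673 in female 2, and 100 to 419 elsewhere. Inflammatory genes were highest in the line labelled female 3 for IL6 (14499), CCL2 (2022) and TNFAIP6 (2418), but CXCL8 was highest in male 3 (2133), the line with the highest S list mean of 9.63.

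Actin genes of muscle separated the lines over a wide range. ACTA2 and ACTC1 were both highest in the youngest donors, at 17653 and 18139 in male 5 and 17158 and 12772 in female 6. They were also high in the adult line female 4, at 15216 and 7836, and low in male 3, at 885 and 556. The line labelled female 3, with the lowest mean correlation with the other standard lines (0.906), had the lowest G2M mean (7.59) and the lowest S list mean (7.56) together with the highest core histone mean (9.22, others at most 8.35).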
